A study of Mus musculus with 24 samples.

How the data were processed

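RNA from brain (a hemisphere, per the labels) and from whole blood of male mice was measured on 1-colour mouse expression arrays (Agilent). The mice were wild type (WT), untreated mice with mucopolysaccharidosis IIIA (MPS IIIA, a lysosomal storage disease caused by loss of the enzyme N-sulfoglucosamine sulfohydrolase, gene Sgsh), and MPS IIIA mice injected with an adeno-associated virus of serotype rh74 (AAV) that carries the human SGSH gene. There were 4 mice per group and 24 arrays, 12 per tissue. Age at collection was 8 months, per the labels. The vector was injected into a vein at 4 to 6 weeks of age, 7 months before collection, at 5e+12 vector genomes per kg. The records list individual mice, so replicates are separate animals, and whether a brain and a blood sample came from the same mouse is not stated by more than a shared replicate number.

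Each sample came with an array file and each tissue with a table of all its samples. The array files hold the intensity of each spot, which the authors deposited as Feature Extraction wrote it: per the file headers, the processed signal is the spot intensity after subtraction of background and removal of spatial trends within the array, on a linear scale, with no step between arrays. The software version is 10.9.1.1 per the file headers and 10.10 per the submitters' processing notes. The tissue tables hold one intensity per non-control spot and sample, which the authors normalized between the 12 arrays of the tissue before they deposited it, by loess as the table is named. They also hold the authors' fold changes, false discovery rates and an adjusted p-value for each comparison, which the authors deposited without naming the test. limma is named in the submitters' processing notes without its role or version.

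The sample records and the tables disagree about which mouse group each array belongs to. Each array's log2 values, centred per probe, were compared with every column of its tissue's table by Pearson's r. The correlation was taken over probes whose mean log2 signal in the tissue lay above the median of all probes. The best column carried the name of another mouse group for 24 of 24 arrays, matched one to one, and always had the array's own replicate number. Each array slide, as named in the file headers, holds the brain and blood arrays of a single mouse group, so the conflict concerns whole slides. Slide 1 holds the WT mice of the records and the AAV-treated mice of the tables. Slide 2 holds the untreated MPS IIIA mice of the records and the WT mice of the tables. Slide 3 holds the AAV-treated mice of the records and the untreated MPS IIIA mice of the tables. Groups here follow the sample records, no sample was moved on account of its values, and results are worded by slide with both names given. Slide and mouse group are the same split, so no fit with slide as a term exists and effects of slide and group cannot be told apart.

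The array files were read in R 4.3.3 with the package data.table, version 1.17.8. Control spots and spots marked as outliers were left out, spots of one probe were averaged as log2 of the processed signal, and each array was centred on its 75th percentile over non-control probes. A log2 value of 0 is thus the 75th percentile of that array. Of 55681 probes, 38107 in brain and 23219 in blood were well above background on at least 4 of the 12 arrays of the tissue and were kept. Probes were named from the tables, and 30994 were matched by gene number to the reference gene table used for symbols. Where several probes shared a name, the one with the highest mean over the 12 arrays stood for it, which left 25729 names in brain and 17608 in blood. Of these, 18890 and 13217 were gene symbols, and the rest were transcripts or regions known by an identifier alone. A gene's change is thus that of 1 probe. No coordinates are given, since the build behind the array design differs from that of the gene table.

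Group means were compared with limma 3.58.1 (lmFit and eBayes with an intensity trend) on all 12 arrays of a tissue, and p-values were two-sided and adjusted by the Benjamini-Hochberg method. A gene was called when its adjusted p was under 0.05. Gene lists, 37 in all with 1 kept for a check of sex, were tested where at least 5 members were measured: 36 lists in brain and 34 in blood. The test was limma's camera with a preset correlation of 0.01 between genes, which asks whether the genes of a list moved more than other genes did. camera with the correlation estimated from the arrays and limma's fry, which asks whether a list's genes moved on balance one way, stood beside it. A list score is the mean log2 distance of the list's genes on an array from their means over the 12 arrays of the tissue. Differences between tissues were tested as interaction terms in a fit of all 24 arrays. Recovery of a gene is the share of its change between WT and untreated mice that is undone in treated mice: 0 leaves the untreated level and 1 restores the WT level. Picking genes by their change inflates it, so it was also computed on splits of the untreated mice and on 20 simulated data sets without any recovery. In the 6 splits the genes were called, and their change from WT taken, with some of the untreated mice. The amount undone was taken with the other untreated mice.

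Genes named for a comparison are Sgsh and, among called genes whose slides do not overlap, the 8 with the largest rise and the 8 with the largest fall. The probe had to be well above background on all 4 arrays of one of the slides, and the name had to be a gene symbol. Up to 4 list members with the smallest p, and 5 genes each way for the tissue differences, were open to naming. Where at most 1 array of a slide was above background and all 4 of the other were, the change is given as a lower bound taken from the lowest signal called above background. This limit was widened from 0 arrays to 1 after the values were seen.

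The groups, tests, gene lists, naming rule and first set of alternatives were fixed before the data were examined. The alternatives were the authors' tables, normexp background correction with an offset of 50, quantile normalization, centring on the median, no filter or a stricter filter on dim probes, the mean over probes, array weights, no intensity trend, a fit of the 2 groups alone, the replicate number as a block, a 2-fold threshold, the other list tests and leaving out each mouse. The mean spot signal named in the plan for normexp was not in the files used here, and the median spot signal took its place. The tissue-specific tables were normalized separately, so they were not used for differences between tissues. Other alternatives were chosen after seeing the data and are named as such in the closing section.

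The limma fits within a tissue and camera with the preset correlation were tested on simulated data, and the other tests were not: arrays were drawn from the real genes' means and spreads, and 50 genes were changed by each of 4 sizes. With a change of 1 on the log2 scale, the test of slide 2 against slide 1 recovered 72% of the changed genes in brain, of 25729 in that step, and 6% in blood, of 17608. With a change of 2 it recovered 96% in brain and 60% in blood. For slide 3 against slide 2, changes of 2 were recovered in 100% in brain and 68% in blood, and for slide 3 against slide 1 in 98% and 52%. A list moved by 1 on the log2 scale was recovered in each of the 6 comparisons, and camera with the preset correlation also called lists that had not been moved: 1, 0 and 2 in the brain comparisons and 1, 1 and 0 in blood. The simulated genes were drawn independently of each other. Genes of a list can be correlated on the real arrays, so these counts can understate false list calls there. The number of arrays limits the precision of every value.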

Results

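Expression in brain and whole blood was measured in 3 groups of 4 male mice, on 24 arrays. The sample records name the groups WT, untreated MPS IIIA and AAV-treated MPS IIIA on slides 1, 2 and 3, and the authors' deposited tables name the same arrays AAV-treated, WT and untreated MPS IIIA. An array and its best table column correlated across probes with r from 0.952 to 0.988 in brain and from 0.72 to 0.939 in blood, while the column of the array's own name gave at most 0.0356 and 0.351. The highest r with any other column was 0.649 in brain and 0.494 in blood. Every comparison below is therefore worded by slide, and each direction drawn from a group name depends on which naming holds. In brain, 63.1% to 69.9% of probes were well above background and the 75th percentile of the signal ran from 484 to 1350. In blood these were 32.2% to 47.2% and 24.3 to 115, so blood arrays were dimmer and their values less precise. Array quality moved with the slides: in brain the share above background was 63.1% to 65.9% on slide 2 and 67.6% to 69.9% on slide 3, without overlap, and 64.4% to 68% on slide 1. In blood the mean slope of the spike-in controls was 0.933 on slide 3 and 0.963 and 0.969 on slides 1 and 2, with no overlap either. Such differences and those of the mouse groups fall on the same split.

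**Figure D1:**
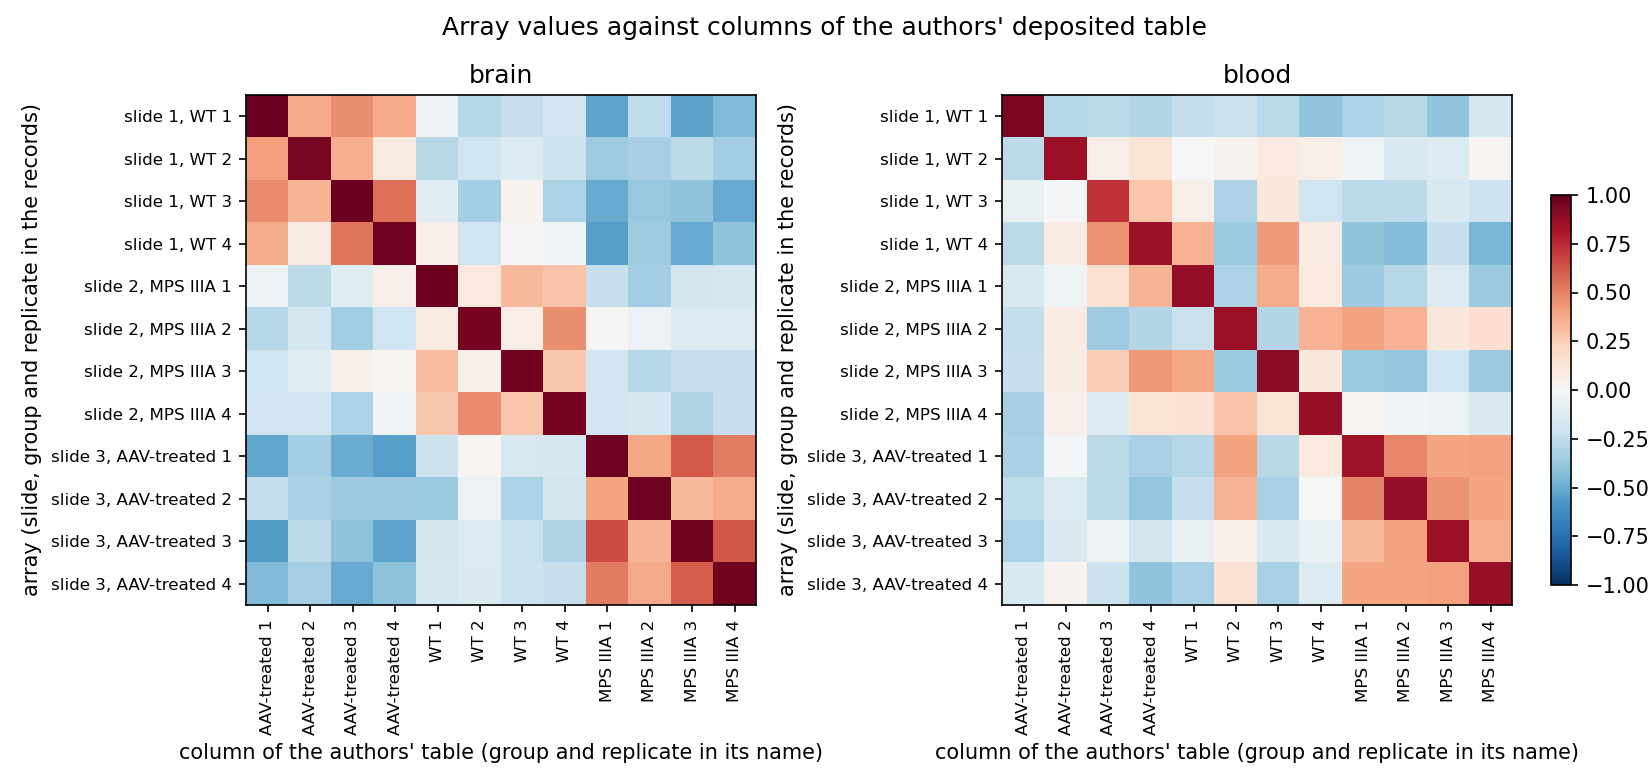
Pearson's r over probes between each array (vertical axis, by slide, group and replicate of the sample records) and each column of the authors' deposited table (horizontal axis, by group and replicate in the column's name), for brain and blood. Each array has a single dark red cell, in a column of another mouse group, with r of at least 0.952 in brain and 0.72 in blood.

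Sgsh, the gene mutated in MPS IIIA, was measured first as the target of the design. Its log2 level in brain was 3.42 ± 0.21 (SD, n = 4) on slide 1, 3.70 ± 0.26 on slide 2 and 3.70 ± 0.21 on slide 3, and in blood 5.19 ± 1.12, 4.88 ± 0.23 and 5.01 ± 0.18. The blood mean of slide 1 was raised by its replicate 1, at 6.86. Without that array the blood changes from slide 1 were 0.235 on slide 2 and 0.37 on slide 3, and with it -0.32 and -0.186. Sgsh was called in none of the 6 comparisons (limma, adjusted p from 0.134 to 0.995). A weaker second probe lay at -0.09 to -0.01 in the brains of slide 1 and at 0.19 to 0.54 in those of slide 3, and with the mean over both probes Sgsh was called there (0.35, adjusted p = 0.0172). Neither probe is read as a check of a label, because the mutation of this mouse model alters the protein without deleting the transcript. The vector carries the human gene, which differs in sequence, and whether the probes also detect its transcript was not tested. Ddx3y, a Y-linked gene, was above background on 24 of 24 arrays and Xist, which is expressed from the inactive X chromosome of females, on 0 or 2 by probe. The 2 were brain replicates 1 and 2 of slide 1 (-4.20 and -4.89, against -7.66 or lower in the other brains), which also stand apart for Pmch below, while their Ddx3y was as in the other brains of the slide (1.08 to 1.48).

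Several arrays stood apart from others of their slide. On slide 2, replicate 2 had an activated microglia score of 0.77 in brain, against -0.86 to -0.77 in the other 3 brains of the slide, -0.45 to -0.15 on slide 1 and 0.52 to 0.94 on slide 3. Gfap, the filament protein of astrocytes, was 3.81 in that brain and 1.55 to 1.91 in the others of the slide. Naglu, which encodes the heparan sulfate enzyme lost in MPS IIIB, was -4.65 in that brain and at least -1.54 in the other 11, and -5.11 in blood replicate 2 of the slide and at least 0.19 in the other 11 blood arrays. The spot was well above background in that brain and not in that blood, and brain and blood of one replicate number are not stated to be one mouse. Alb, the liver's albumin gene, was 11.64 on blood array 1 of slide 1 and at most 1.02 on the other 11 blood arrays. In brain Alb lay between 0.03 and 3.48 on slide 1, at -0.61 on replicate 2 of slide 3 and at most -5.05 on the other 7 arrays. Prm1, a sperm protamine, reached 5.09 in brain replicate 2 of slide 3 and at most -1.44 in the other brains. Pmch, a hypothalamic neuropeptide, was -3.21 and -3.67 in brain replicates 1 and 2 of slide 1 and at least 2.00 in the other brains. These arrays were kept, and counts without them are given where they differ.

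**Figure D2:**
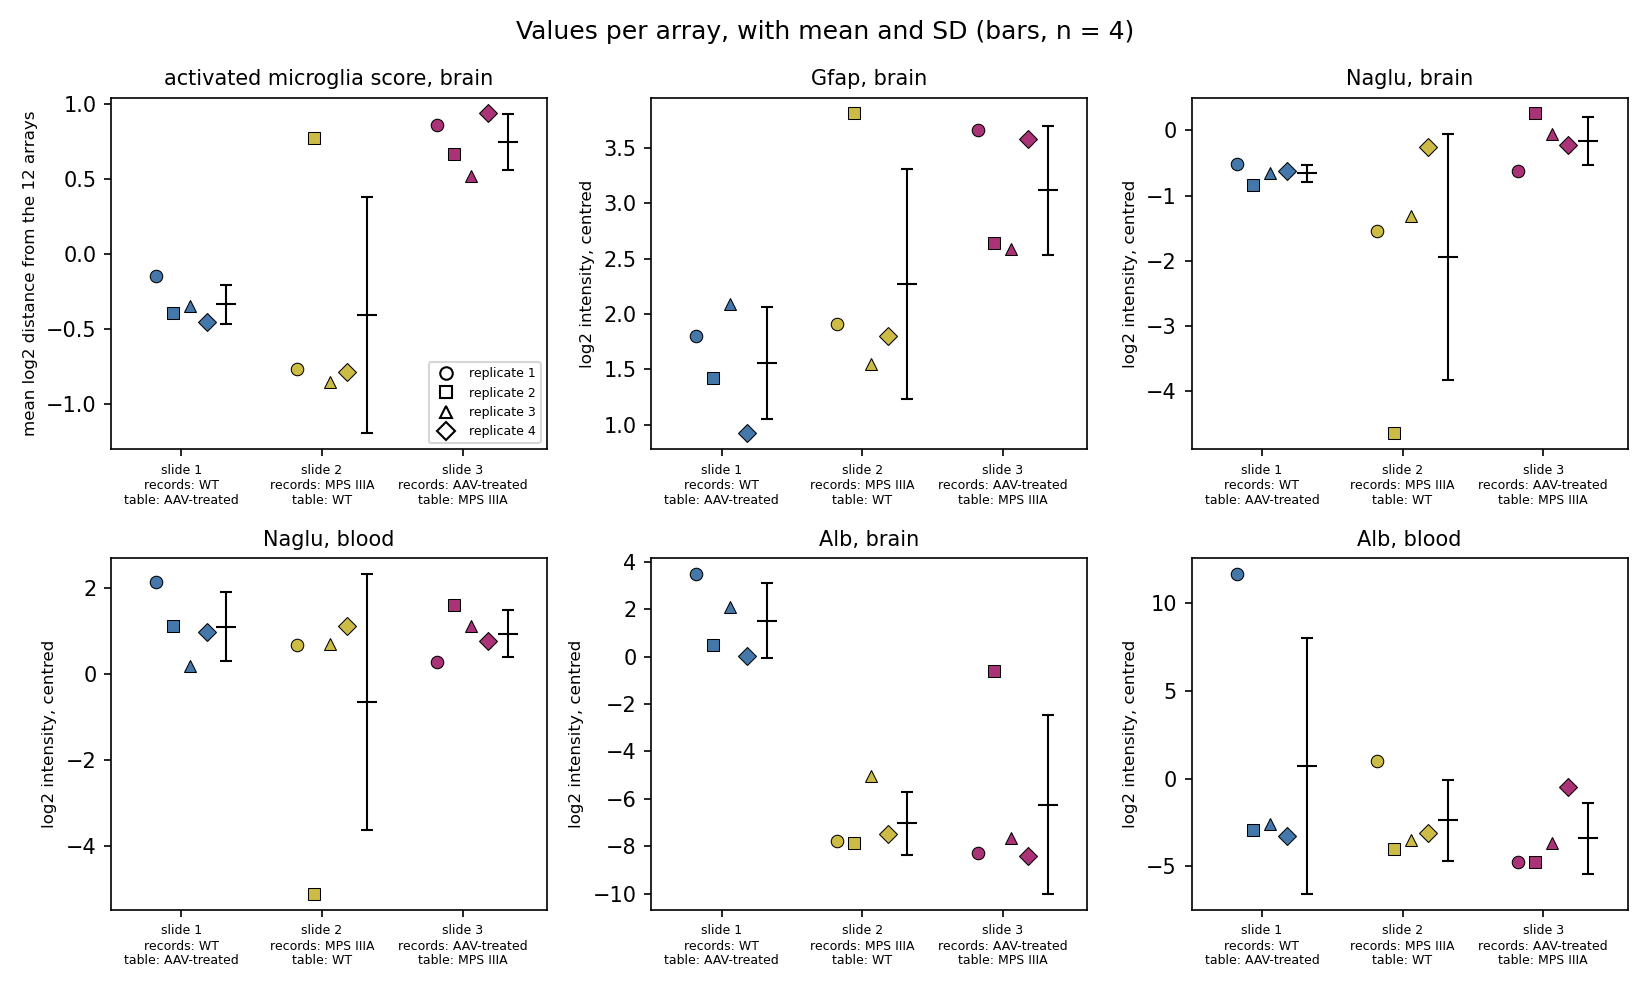
Activated microglia score (mean log2 distance from the mean of the 12 brains) and centred log2 intensities of Gfap, Naglu and Alb on single arrays by slide, each tick with both group names, symbols for the replicate and bars for the mean and SD of 4 arrays. Replicate 2 of slide 2 lies at 0.77 for the score and at -4.65 (brain) and -5.11 (blood) for Naglu.

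Slide 2 against slide 1 in brain is the effect of the disease by the records' names (untreated MPS IIIA against WT), and WT against AAV-treated mice by the tables' names. camera with the preset correlation called the lists of the unfolded protein response, heat shock proteins, cerebellar neurons and immediate early genes, which neural activity induces, lower on slide 2. With an estimated correlation it called 0 lists (smallest adjusted p = 0.787), and only 5 of 15 heat shock genes and 3 of 22 immediate early genes were called lower, with 1 of the latter higher. Transcripts made by liver were far lower: Alb was at least 128-fold lower (adjusted p = 0.00681), as a bound since it was above background in 1 of 4 brains of slide 2, and the 8 genes named as falling were all liver-secreted proteins. Alb was also high on blood replicate 1 of slide 1 and in brain replicate 2 of slide 3, and whether liver RNA entered the samples at dissection was not tested, so these falls are not read as a change in brain tissue. Slc6a3, the dopamine transporter of midbrain neurons, was 3.17 ± 0.46 (SE) higher on the log2 scale (9.00-fold, adjusted p = 0.00386), and 2.10 higher without brain replicates 1 and 2 of slide 1, which are low in hypothalamic transcripts and lowest for this gene (-3.68 and -2.78, against -1.13 and -1.05). Genes of activated microglia had a median change of 0.04 with 0 of 30 called. Without brain replicate 2 of slide 2 their median was -0.26 with 7 lower and 0 higher (camera adjusted p = 0.000116; adjusted p = 0.717 with an estimated correlation). That brain was left out for its high microglia and astrocyte values, so a fall of such genes follows in part from the choice. camera with the preset correlation then also called complement (2 of 14 genes lower, adjusted p = 0.000804; 0.543 with an estimated correlation) and reactive astrocytes (1 of 24, 0.00369; 0.717), but not lysosomes (2 of 48, 0.15; 0.717).

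In that comparison 12 of the 22 measured genes of the unfolded protein response were lower and none higher, a count of 16 lower when adjusted over the list alone, with a median of -0.49 (camera adjusted p = 1.21e-08; adjusted p = 0.787 with an estimated correlation). Dnajb9, a chaperone of the endoplasmic reticulum, fell by 0.40 ± 0.07 (adjusted p = 0.00603) and Xbp1, a transcription factor of this response, fell by 0.86 ± 0.17 (adjusted p = 0.0108). Of 14 cerebellar genes 7 were lower, 12 when adjusted over the list alone, with a median of -0.73 (camera adjusted p = 1.73e-06; adjusted p = 0.932 with an estimated correlation), among them Gabra6, a receptor subunit of cerebellar granule cells, at -1.19 ± 0.24. The cerebellar score varied within slide 2 from -1.23 to 0.27. Of 15 heat shock genes 5 were lower, 9 when adjusted over the list alone, including the co-chaperone Bag3 at -0.70 ± 0.16 and Hspa4l at -0.43 ± 0.10 (camera adjusted p = 0.000138; adjusted p = 0.932 with an estimated correlation). Of 22 immediate early genes 3 were lower and 1 higher, 5 and 1 when adjusted over the list alone, with Ier2 at -0.66 ± 0.14 and Ier5 at -0.55 ± 0.14 (camera adjusted p = 0.00428; adjusted p = 0.932 with an estimated correlation). Of 39 ribosomal protein genes 37 had a positive change with a median of 0.13, yet 0 were called by limma over all genes or when adjusted over the list alone (camera adjusted p = 0.00472; adjusted p = 0.932 with an estimated correlation). Of the 36 lists camera called 5, and 10 without replicate 2 of slide 2, and fry called 2.

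Most of the other large rises were of genes with low signal on slide 1, Psmc3ip less so (-2.44). Myl10, a myosin light chain, was 2.06 ± 0.24 higher (adjusted p = 0.00158), of uncertain size since it was above background on 2 of 4 arrays of slide 1, Psmc3ip 1.88 ± 0.55, Ttn, the muscle protein titin, 1.80 ± 0.42 and Mid1 1.63 ± 0.30. Pitx1, a transcription factor of pituitary and hindlimb, and Obox3, an oocyte homeobox gene, were not above background on slide 1 and were at least 1.51-fold and 2.85-fold higher on slide 2, and Trat1, a T cell adaptor above background on 1 array of slide 1, at least 3.23-fold. The falls were Alb, Ahsg (at least 101-fold), the major urinary protein genes Mup18 (-7.95 ± 1.36), Mup9 (-7.92 ± 1.35), Mup19 (-7.49 ± 1.25), Mup17 (-7.32 ± 1.26) and Mup20 (at least 90.8-fold), and Serpina3k, not above background on slide 2 and at least 36.6-fold lower there. Without the brains of slide 1 with low hypothalamic transcripts some genes were not called, with only 2 arrays left on that slide. Psmc3ip (1.80, adjusted p = 0.156), Ttn (1.91, 0.0628) and Hspa4l (-0.43, 0.0752) had changes about as large as before, and those of Ier5 (-0.37, from -0.55, adjusted p = 0.137) and Ier2 (-0.54, from -0.66, 0.0846) were smaller. The differences of the means, with a slide at background in each, went from 2.30 to 1.59 for Pitx1 (0.091) and from -7.09 to -6.40 for Serpina3k (0.0589). The score of a list of liver genes chosen after these values were seen was 1.33 to 4.08 in the brains of slide 1 and -1.96 to -0.87 in those of slide 2.

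limma called 2810 of 25729 names between slides 2 and 1 in brain, 1559 higher and 1251 lower on slide 2. Among gene symbols alone the balance turned, with 970 higher and 1072 lower. Of all called names, 385 changed by at least 2-fold. The 4 arrays of each slide did not overlap for 17.6% of all names, where chance gives 2.86%. The count was 1487 without replicate 2 of slide 2, 1224 without its replicate 4 and 1597 without replicate 3 of slide 1. It was 1434 without the brains of slide 1 with low hypothalamic transcripts, and centring on probes detected on all arrays changed the split to 2005 higher and 1054 lower.

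Slide 3 against slide 2 in brain tests the treatment by the records' names (AAV-treated against untreated MPS IIIA) and the disease by the tables' names (untreated MPS IIIA against WT). camera with the preset correlation called the lists of activated microglia, reactive astrocytes, complement, the interferon response, antigen presentation, neutrophils and lysosomes higher on slide 3, and that of the mitochondrial respiratory chain lower. With an estimated correlation it called 0 lists (smallest adjusted p = 0.721), and most genes of several lists were not called, such as 5 of 19 higher for antigen presentation and 10 of 33 for the interferon response. Trem2, a lipid receptor of microglia, rose from 2.02 ± 0.74 (SD, n = 4) to 3.56 ± 0.32, a change of 1.54 ± 0.29 (SE; 2.91-fold, adjusted p = 0.00251). C4b, a complement component, was 1.51 ± 0.37 higher (2.85-fold, adjusted p = 0.0113), although replicate 2 of slide 2 overlapped slide 3.

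The activated microglia list had 18 of 30 measured genes higher on slide 3 and 1 lower, 24 and 1 when adjusted over the list alone, with a median of 1.02 (camera adjusted p = 1.51e-07; adjusted p = 0.721 with an estimated correlation). Cd63, a membrane protein of lysosomes and endosomes, was 0.74 ± 0.14 higher (adjusted p = 0.0021). Reactive astrocyte genes were higher in 7 of 24 and lower in none, 8 when adjusted over the list alone, with a median of 0.56, including the intermediate filament Vim at 0.87 ± 0.17 and the transcription factor Stat3 at 0.48 ± 0.07 (camera adjusted p = 8.99e-05; adjusted p = 0.721 with an estimated correlation). Complement genes were higher in 7 of 14, 11 when adjusted over the list alone, and all 14 had a positive change, with properdin (Cfp) at 0.51 ± 0.13 (camera adjusted p = 0.000286; adjusted p = 0.721 with an estimated correlation). Interferon response genes were higher in 10 of 33 and lower in 1, with the same counts when adjusted over the list alone. Among them were Oas2 at 0.78 ± 0.14 and Gbp3 at 0.49 ± 0.10 (camera adjusted p = 0.000172; adjusted p = 0.721 with an estimated correlation). Antigen presentation genes were higher in 5 of 19, 6 when adjusted over the list alone, with the MHC class II chain Cd74 at 1.05 ± 0.17 and H2-DMb1 at 0.91 ± 0.21 (camera adjusted p = 0.0174; adjusted p = 0.783 with an estimated correlation).

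Lysosomal genes were higher in 16 of 48 and lower in 2, 19 and 3 when adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.000289; adjusted p = 0.721 with an estimated correlation). Gusb, the lysosomal beta-glucuronidase, was 0.60 ± 0.08 higher (adjusted p = 0.000301), and Sumf1, which activates sulfatases, was 0.60 ± 0.08 higher (adjusted p = 0.000251). Of 33 respiratory chain genes 14 were lower and 2 higher, 18 and 3 when adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.0198; adjusted p = 0.988 with an estimated correlation). Sdha, a subunit of complex II, fell by 0.39 ± 0.05, while Uqcrb, a subunit of complex III, was 0.60 ± 0.07 higher. Neutrophil genes were higher in 7 of 20 and lower in 2, 10 and 2 when adjusted over the list alone (camera adjusted p = 0.0431; adjusted p = 0.765 with an estimated correlation). S100a9 was 1.26 ± 0.28 higher and the elastase gene Elane 0.45 lower (-0.45 ± 0.12). Without replicate 2 of slide 2, left out after its values were seen, the activated microglia list had 24 genes higher and 1 lower with a median of 1.17, and complement 10 of 14 with a median of 0.87. camera called 8 of the 36 lists and fry 7, and camera called 5 without replicate 3 of slide 2.

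**Figure D3:**
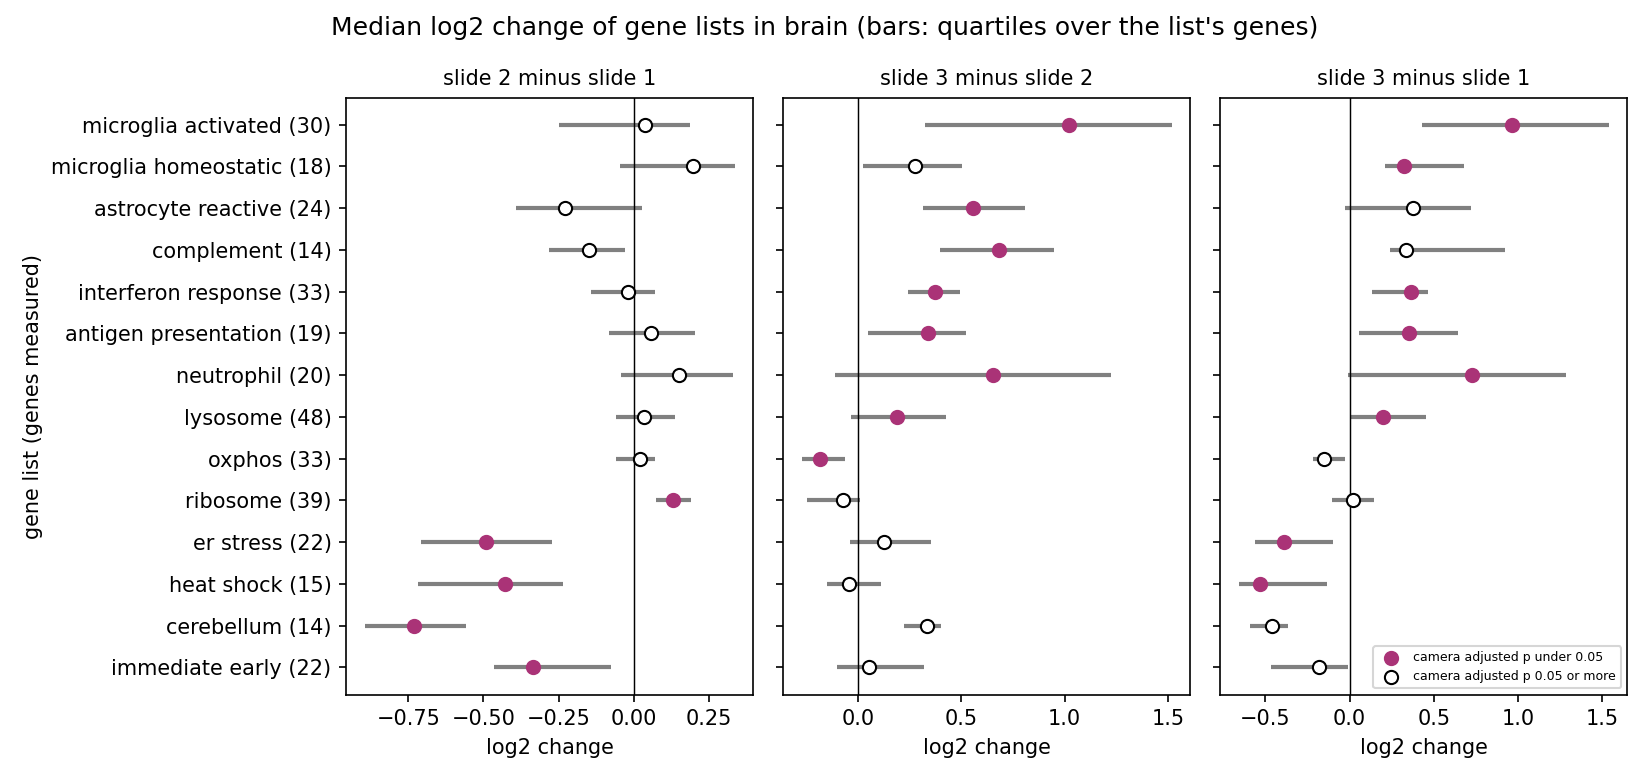
Median log2 change of 14 gene lists in brain for slide 2 minus slide 1, slide 3 minus slide 2 and slide 3 minus slide 1 (horizontal axes, separate scales); bars span the quartiles over the genes of a list, and filled points have a camera adjusted p under 0.05 with the preset correlation. Activated microglia genes lie at 0.04, 1.02 and 0.97.

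Of the 8 genes with the largest rises on slide 3 against slide 2, 5 were not above background on slide 2. Glycam1, a mucin of lymph node vessels, was at least 2.70-fold higher, Scgb1b7 at least 5.36-fold, Krt6a at least 2.42-fold, Wfdc21 at least 2.07-fold and Treml2, a receptor of myeloid cells and lymphocytes, at least 1.74-fold. Tnfsf8 (at least 1.61-fold, above background on 1 array of slide 2), Serpinf2 (1.98 ± 0.54) and Prl2c5 (1.88 ± 0.63) were also higher, the last above background on 2 of 4 arrays of slide 2, so of uncertain size. Without the slide 1 brains with low hypothalamic transcripts, which are not in this comparison, Prl2c5 kept its change and was not called (adjusted p = 0.0503). The largest falls were Obox6 (at least 2.72-fold, above background on 1 array of slide 3), the olfactory receptor genes Olfr715b (-2.51 ± 0.38) and Olfr1466 (-2.08 ± 0.28), Pom121l2 (-2.46 ± 0.35), Spatc1 (-2.37 ± 0.42, of uncertain size with 2 of 4 arrays of slide 3 above background), the vomeronasal receptor gene Vmn1r240 (-2.24 ± 0.27), Zfp345 (-2.01 ± 0.22) and Ms4a19 (-1.92 ± 0.20). limma called 6224 names, 2579 higher and 3645 lower on slide 3. Among gene symbols alone the balance turned, with 2224 higher and 2009 lower. Of all called names, 728 changed by at least 2-fold. With centring on the array median 2626 were higher and 2468 lower, and no list was called lower, the respiratory chain included. The slides did not overlap for 28.1% of names, where chance gives 2.86%. Among 568 genes with more than 1 called probe, probes of the same gene went opposite ways in 157.

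Slide 3 against slide 1 in brain compares AAV-treated MPS IIIA with WT mice by the records' names and untreated with AAV-treated MPS IIIA mice by the tables' names. By camera with the preset correlation slide 3 was higher in the lists of activated and resting microglia, lysosomes, antigen presentation, the interferon response and neutrophils, and lower in those of the unfolded protein response and heat shock. With an estimated correlation 0 lists were called (smallest adjusted p = 0.813). Activated microglia genes were higher in 21 of 30 and lower in none, 25 when adjusted over the list alone, with a median of 0.97 (camera adjusted p = 8.95e-06; adjusted p = 0.813 with an estimated correlation). Lgals3bp was 1.12 ± 0.17 higher (2.17-fold, adjusted p = 0.000356) and Cd63 0.85 ± 0.14 (adjusted p = 0.000559).

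In the same comparison lysosomal genes were higher in 21 of 48 and lower in 5, with equal counts when adjusted over the list alone, with the mannosidase Man2b1 at 0.77 ± 0.10 and Gusb at 0.58 ± 0.08 (camera adjusted p = 0.00936; adjusted p = 0.813 with an estimated correlation). The other 6 lists had a camera adjusted p of 0.0214 and an adjusted p of 0.813 with an estimated correlation. Antigen presentation genes were higher in 8 of 19 and lower in 1, 9 and 1 when adjusted over the list alone, with Cd74 at 1.18 ± 0.17 and H2-DMb1 at 1.19 ± 0.21. Interferon response genes were higher in 8 of 33 and lower in 1, with Trim30a at 0.99 ± 0.18 and Ifi27 at 0.57 ± 0.10. Resting microglia genes were higher in 7 of 18, 8 when adjusted over the list alone, with Aif1 at 1.02 ± 0.15, while the integrin Itgam was lower by a change of -0.93 ± 0.11. Neutrophil genes were higher in 9 of 20, with S100a9 at 1.40 ± 0.28 and Mpo at 1.25 ± 0.20. Of 22 unfolded protein response genes 10 were lower, with Manf at -1.08 ± 0.23 and Ddit3 at -0.44 ± 0.09, and of 15 heat shock genes 7, with Hsp90aa1 at -0.93 ± 0.09 and Hspe1 at -0.60 ± 0.11. fry called 9 lists.

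Single genes with the largest rises on slide 3 against slide 1 were Prm1 (at least 27.7-fold, above background on 1 array of slide 1), Myl10 (3.65 ± 0.24), Cga, a pituitary hormone subunit (at least 6.72-fold, likewise), Sult1c2 (3.18 ± 0.59) and Slc6a3 (3.15 ± 0.46). Myl10 and Sult1c2 were above background on 2 of 4 arrays of slide 1, so the sizes of their rises are uncertain. Without the brains of slide 1 with low hypothalamic transcripts Slc6a3 was 2.08 higher, and 4 genes were not called with fewer arrays. Their differences of means, with a slide mostly at background in each, were 5.52 for Prm1 (from 5.33, adjusted p = 0.0632), 4.69 for Tnp2 (from 4.49, 0.072), -6.86 for Fabp1 (from -7.22, 0.057) and 2.70 for Cga (from 3.49, 0.215). Tnp2, a sperm protein, was at least 6.63-fold higher, and brain replicate 2 of slide 3 raises this bound (2.24, against -5.88 to -3.80 in the other 3 of the slide) and that of Prm1. Without that brain the difference of the means fell from 5.33 to 3.32 for Prm1 and from 4.49 to 2.66 for Tnp2, with slide 1 mostly at background in each. Scgb1b7 was higher by at least 6.58-fold and Hsfy2 by at least 4.78-fold, and none of the 3 was above background on slide 1. The largest falls were again liver or gut transcripts: Mup9 (-7.48 ± 1.35, of uncertain size with 2 of 4 arrays of slide 3 above background) and, each above background on 1 array of slide 3 and given as a lower bound, Alb (96.4-fold), Ahsg (71.7-fold), Fabp1 (87.8-fold), Mup20 (74.8-fold) and Fabp2 (33-fold). Cyp2c50 and Serpina4-ps1 were at least 8.69-fold and 15.7-fold lower. limma called 9496 names, 4427 higher and 5069 lower on slide 3. Among gene symbols alone the balance turned, with 3532 higher and 3270 lower. With centring on probes detected on all arrays, 4764 of all names were higher and 4735 lower. With the main centring, 1481 called names changed by at least 2-fold. The slides did not overlap for 35.3% of names, where chance gives 2.86%, and of 1418 genes with more than 1 called probe 377 had probes that went opposite ways.

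Slide 2 against slide 1 in blood asks whether the disease leaves a mark in blood by the records' names, and compares WT with AAV-treated mice by the tables' names. camera with the preset correlation called the lists of T cells, ribosomes and antigen presentation higher and that of neutrophils lower on slide 2, with or without the liver-rich array of slide 1. With an estimated correlation it called 0 lists (smallest adjusted p = 0.704), and limma called 0 of 17608 names (smallest adjusted p = 0.467), against 1747 at an unadjusted p under 0.05, and fry called 0 of 34 lists. The median change over all names was 0.17, so list medians are read against that shift, and with centring on the array median the shift was 0.68. With the preset correlation camera called 14 lists, 9 higher and 5 lower, and none with an estimated correlation (adjusted p from 0.704 to 0.708).

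The lists with a higher median were ribosomal proteins (0.56, 39 of 39 genes positive, camera adjusted p = 2.46e-07), T cells (0.88, 22 of 24, 5.81e-05), B cells (0.92, 19 of 19, 0.000134), cell division (0.65, 20 of 21, 0.00084) and antigen presentation (0.51, 19 of 19, 0.0015). Natural killer cells (0.70, 18 of 20, camera adjusted p = 0.0119), activated microglia genes, which monocytes also express (0.42, 23 of 27, 0.0147), eosinophils and basophils (0.94, 10 of 11, 0.0186) and platelets (0.70, 18 of 21, 0.0475) followed. Lower medians were seen for neutrophils (-0.92, 7 of 25 positive, camera adjusted p = 1.89e-05), cholesterol synthesis (-0.62, 2 of 23, 0.00084), autophagy (-0.12, 10 of 24, 0.0119), the respiratory chain (-0.13, 12 of 33, 0.0393) and heparan sulfate synthesis (-0.24, 8 of 23, 0.0497). Adjusted over the list alone, called genes numbered 6 for cell division, 3 each for activated microglia and eosinophils and basophils, 1 for natural killer cells, 1 higher and 1 lower for neutrophils, 1 higher for heparan sulfate synthesis and 0 for the other lists. The array of slide 1 with liver transcripts had the highest score of its slide for cholesterol synthesis (3.17) and the respiratory chain (1.06), and the lowest for B cells (-2.45), eosinophils and basophils (-2.26), natural killer cells (-1.87), T cells (-1.75) and antigen presentation (-1.29), among others. Without it 4 of the 14 lists kept their call: ribosomal proteins (median 0.27, camera adjusted p = 0.00227), T cells (0.45, 0.0442), antigen presentation (0.31, 0.0442) and neutrophils (-1.16, 3.06e-06). Cholesterol synthesis (0.47, 0.00977) and the respiratory chain (0.29, 0.0334) were then called higher instead of lower, and the other 8 were not called. Lists called only without it were the interferon response (-0.26, 0.000286), immediate early genes (-0.51, 0.000791), hypothalamus and pituitary (-0.44, 0.0195) and lysosomes (0.26, 0.0442). No list was called with an estimated correlation in that setting either (adjusted p of at least 0.708).

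Slide 3 against slide 2 in blood is the treatment effect by the records' names and the disease effect by the tables' names. camera with the preset correlation called the neutrophil and interferon response lists higher on slide 3 and the red cell list lower, and 0 lists with an estimated correlation. Neutrophil genes had a median change of 1.26, with 22 of 25 positive (camera adjusted p = 2.13e-06; adjusted p = 0.962 with an estimated correlation). Interferon response genes had a median of 0.53, with 29 of 33 positive (camera adjusted p = 4.85e-05), and red cell genes one of -0.66, with 4 of 27 positive (camera adjusted p = 0.000368); both had an adjusted p of 0.962 with an estimated correlation. No member of these lists was called by limma over all genes, and 1 neutrophil and 2 interferon response genes were when adjusted over the list alone. camera called 3 lists, 5 without replicate 1 or 4 of slide 2, and fry called 0.

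limma called 6 of 17608 names between slides 3 and 2 in blood, each with an adjusted p of 0.0481, and 1838 had an unadjusted p under 0.05. Tcp11, a gene of testis and sperm, rose from -2.18 ± 0.57 (SD, n = 4) to 0.55 ± 0.33, a change of 2.73 ± 0.40 (6.63-fold), with 2 of 4 arrays of slide 2 above background, so the size of the rise is uncertain. The 5 that fell were Cryaa, a lens crystallin that was above background on 0 arrays of slide 3 and 1 of slide 2, so that its fall has no firm size, and 4 transcripts known only by an identifier. The count was 0 without replicate 1, 3 or 4 of slide 2, without replicate 1, 2 or 4 of slide 3 and without replicate 2 or 4 of slide 1. It was 1 without replicate 3 of slide 3, 10 without replicate 2 of slide 2 and 383 without replicate 1 of slide 1, the array with liver transcripts. With array weights it was 3102, and without replicate 1 of slide 1 and replicate 2 of slide 2, chosen after their values were seen, 2513.

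Slide 3 against slide 1 in blood compares AAV-treated MPS IIIA with WT mice by the records' names and untreated with AAV-treated MPS IIIA mice by the tables' names. camera with the preset correlation called the lists of ribosomes, antigen presentation, B cells, platelets, natural killer cells, monocytes and activated microglia higher on slide 3. With an estimated correlation (adjusted p = 0.801 for each) and by fry it called 0 lists, and few of their genes were called: 0 for B cells and natural killer cells, 1 for platelets and 2 of 39 for ribosomes. H2-Eb1, an MHC class II chain, rose from 4.93 ± 1.89 (SD, n = 4) to 8.93 ± 0.64, a change of 4.01 ± 0.98 (16.1-fold, adjusted p = 0.0495). Ltf, the lactoferrin gene of neutrophil granules, was 3.74 ± 0.86 higher (13.3-fold, adjusted p = 0.0454), and Mpo, another granule gene, was at least 9.84-fold higher. The neutrophil list as a whole was not called, with a median of 0.29 (camera adjusted p = 0.712). Without the liver-rich array of slide 1 its median was -0.076 (camera adjusted p = 0.839).

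Lists were read against a median change of 0.18 over all names. All 39 ribosomal protein genes had a positive change with a median of 0.72; 2 were called, Rps15 and Rps18 (1.21 ± 0.27), and 17 when adjusted over the list alone (camera adjusted p = 4.06e-07). Antigen presentation genes had a median of 0.92 and 2 called, 10 when adjusted over the list alone, with Psmb10 at 1.13 ± 0.27 beside H2-Eb1 (camera adjusted p = 0.000505). B cell genes had a median of 1.23 with 19 of 19 positive and 0 called, also 0 when adjusted over the list alone (camera adjusted p = 0.00488). Activated microglia genes, with Trem2 at 2.23 ± 0.51 and Itgax at 1.52 ± 0.32, had a median of 0.79 and 3 called, 8 when adjusted over the list alone (camera adjusted p = 0.00778). Platelet genes had a median of 0.89, with Treml1 at 2.26 ± 0.50 called (camera adjusted p = 0.0166), natural killer cell genes 0.74 with 0 called (0.0221), and monocyte genes 0.79 with 2 called, Ear2 (2.05 ± 0.37) and Cd300e (1.42 ± 0.27), 3 when adjusted over the list alone (0.0492). All 7 lists had an adjusted p of 0.801 with an estimated correlation, and fry called 0. Without replicate 1 of slide 1, the liver-rich array with the lowest scores of its slide for all 7, only ribosomal proteins (0.44, camera adjusted p = 0.000829) and antigen presentation (0.74, 0.014) kept their call. B cells (0.56, 0.231), activated microglia (0.48, 0.0929), platelets (0.41, 0.252), natural killer cells (0.33, 0.517) and monocytes (0.24, 0.406) lost it. Red cell (-0.69, 0.000206) and immediate early genes (-0.56, 0.014) were then called lower. With an estimated correlation none of these calls held in that setting (adjusted p = 0.939 for each). camera called 12 lists without replicate 4 of slide 3, and 4, 15, 15 and 12 without replicates 1 to 4 of slide 1.

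Other large rises were Marco, a scavenger receptor of macrophages (2.80 ± 0.52), H2-Oa (2.42 ± 0.59), Dcaf12l2 (2.37 ± 0.49) and Cbr2 (2.27 ± 0.47), and Nxpe4 was at least 3.24-fold higher. Car14, a carbonic anhydrase, fell by 3.57 ± 0.71, of uncertain size with 2 of 4 arrays of slide 3 above background, and the other large falls were of transcripts not above background on slide 3: Obox1 was at least 5.19-fold lower, Olfr704 3.51-fold, Ccdc151 2.94-fold, Rbmy 2.40-fold, Theg 2.36-fold, Olfr332 2.31-fold and Glp2r 2.04-fold, each as a lower bound. limma called 477 of 17608 names, 267 higher and 210 lower, and the slides did not overlap for 17.8% of names, where chance gives 2.86%. With centring on probes detected on all arrays, chosen after seeing the data, 299 were called, 66 higher and 233 lower, so the share of called names that were higher depends on the centring. With centring on the array median the median change over all names was 0.73 and 42 were called.

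Single arrays decided that count. It was 2733 without replicate 1 of slide 1, the array with liver transcripts, and 1097 without replicate 2 of that slide. It was 7 and 5 without its replicates 3 and 4. Without replicates 1, 3 and 4 of slide 2 it was 90, 247 and 42, and without replicates 1 to 4 of slide 3 it was 7, 4, 5 and 5.

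Whether blood and brain change together was asked by the study. Across 17013 genes measured in both tissues, the changes of slide 3 against slide 2 correlated with Pearson's r of 0.557 and Spearman's rho of 0.565, and 70.5% of genes had the same sign. Genes are not independent replicates, so no p is given. Over 12863 gene symbols r was 0.499, and over 4150 transcripts known by an identifier 0.633. For slide 2 against slide 1, r was 0.224 and rho 0.179 with the same sign in 56.1% of genes, and r was 0.047 without blood replicate 1 of slide 1, the array with liver transcripts, 0.142 without the genes high on that array, and 0.029 without a pair of arrays per tissue that stand apart, both settings chosen after seeing the data, so this relation rests on a few arrays. For slide 3 against slide 1 r was 0.478. Over 8908 probes at background on every array r was 0.075 for slide 3 against slide 2, 0.044 for slide 2 against slide 1 and 0.086 for slide 3 against slide 1. Each slide holds both tissues of 1 mouse group, so an effect of the slide alone could relate the tissues in each comparison. Such an effect and one of the mouse group cannot be told apart here, and probes at background need not show it.

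The difference between tissues was tested as an interaction over 17013 genes. limma called 0 for slide 2 against slide 1 (1751 at an unadjusted p under 0.05; 304 without blood replicate 2 of slide 1, 14 without its replicate 1, and 3 and 10 without blood replicates 1 and 3 of slide 2). For slide 3 against slide 2 it called 2. One was Cryaa, whose blood change lies at background and is not given. That count was 59 without blood replicate 1 of slide 1, 22 and 9 without blood and brain replicate 2 of slide 2, and 5 without blood replicate 2 of slide 1. For slide 3 against slide 1, a comparison not planned, it called 176, with the change higher in blood for 112 and in brain for 64. Marco (-0.37 in brain, 2.80 in blood), Batf3 (-0.15 and 1.89) and Treml4 (-0.89 and 1.36) were among the former. Hcar2, a receptor of microglia and neutrophils, was among the latter: it rose by at least 0.55 in brain, where it was not above background on slide 1, and changed by -0.67 in blood.

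How far treatment undid the disease effect depended on the naming. By the records' names, 2810 genes called between untreated and WT brains had a median recovery of 0.14 in treated brains, with 1600 closer to WT (56.9%). Splits of the mice gave medians from -0.05 to 0.19, and simulated data without recovery gave 0.09 with 63.9% closer to WT over the 5586 genes they called. By the tables' names, 6224 genes had a median recovery of 0.91 with 5809 closer to WT (93.3%), splits gave 0.67 to 0.89, and simulated data gave 0.06 with 60.3% closer over 8265 genes. By these names slide 3 is set against both other slides, so an effect of slide 3 alone would also give values near 1. The splits kept the slides and the simulated data held no slide effect, so neither addresses this. In blood no gene was called between the groups that the records name untreated and WT, so recovery has no value there, and by the tables' names 6 genes had a median of 0.75, where simulated data gave 0.17 over more genes. By the records' names the brain value was 0.20, 0.19 and 0.23 without replicates 1, 2 and 3 of slide 2, 0.19 without replicate 1 of slide 3 and 0.11 without replicate 2 of slide 1.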

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

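The tests of the label conflict and of the replicate that stands apart on slide 2 were chosen only after the results were seen, while the regroupings of the samples and the test of the array slide were planned before the data were examined. An array was taken as far from the others of its slide when its gap to the nearest of them, divided by the range of the 4 arrays, passed Dixon's 95% limit. In the paragraphs on such far arrays below, each value in parentheses is this ratio and not a level or score. Of 552 groups of 4 arrays, genes and list scores together, 52 had such an array. Chance gives about 1 in 20, which is 28 here, so many of the single values below need no cause.

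The brain of replicate 2 of slide 2 had the highest values of its slide for the activated microglia list (0.943), C4b (0.943), Trem2 (0.839) and the mannosidase gene Man2b1 (0.846). It was also the highest for Olfr715b (0.945) and Sult1c2 (0.92), and the lowest for the circadian clock list (0.877) and Prm1 (0.867). The blood array of that replicate number was the lowest of its slide for Naglu (0.931).

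Liver transcripts stood out on a few arrays. The brain of replicate 2 of slide 3 was the highest of its slide for the liver list (0.971), Serpina3k (0.951), Mup19 (0.931), Alb (0.907), Mup20 (0.898), Mup17 (0.89), Mup18 (0.873) and Ahsg (0.859). It was the lowest for the GABA neuron list (0.909) and Dnajb9 (0.849). The brain of replicate 3 of slide 2 was the highest of its slide for Mup19 (0.943), Fabp2 (0.892), Fabp1 (0.891), Alb (0.864) and Ahsg (0.846), and the lowest for the neutrophil list (0.862). The blood of replicate 1 of slide 1 was the highest of its slide for the liver list (0.95), Sgsh (0.877) and the cholesterol synthesis list (0.854), and the lowest for the natural killer cell list (0.951), the endothelium list (0.906) and Obox1 (0.883).

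The other far arrays showed no common theme. In brain on slide 1, replicate 4 was high for the unfolded protein response list (0.836) and replicate 1 for the plasma cell list (0.931). On slide 2, replicate 4 was high for the heparan sulfate degradation list (0.951), and replicate 1 for Ttn (0.831) and Ier5 (0.836). On slide 3, replicate 4 was high for the autophagy list (0.839), and replicate 1 was high for Psmc3ip (0.874) and Mpo (0.838) and low for the endothelium list (0.89) and Vmn1r240 (0.87). Replicate 3 of that slide was high for Obox6 (0.905) and Sumf1 (0.854) and low for Zfp345 (0.869).

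In blood, the slope of the spike-in controls on replicate 4 of slide 2 was 0.950, the lowest of its slide (0.956), and replicate 1 had a high striatum list (0.932). On slide 3, replicate 4 was high for the activated microglia list (0.931) and low for the resting microglia list (0.845), and replicate 2 was low for Car14 (0.931) and the autophagy list (0.858). Replicate 1 was high for the natural killer cell list (0.836) and replicate 3 for Theg (0.987).

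Some genes changed differently in brain and blood by a test of the difference itself. For slide 3 against slide 1 the brain change was higher for the carbonic anhydrase gene Car14 (by 4.204, of uncertain size since 2 of 4 blood arrays of slide 3 were above background), and by at least 1.225 for the receptor gene Hcar2, 1.64 for Ccdc151 and 2.01 for Nes, which encodes the intermediate filament nestin. It was lower for Marco (-3.17), Ear10 (-2.69), Treml4 (-2.25) and Batf3 (-2.03), and for Chil5 (-2.18 or lower). The bounds stand for genes not above background on any array of a slide in one of the tissues.

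The sample records and the authors' tables give every array to different mouse groups. Activated microglia genes were higher on slide 3 than on slide 2 with a median of 1.02 (camera adjusted p = 1.51e-07; 0.721 with an estimated correlation), which is consistent with the tables' names, by which slide 3 holds untreated MPS IIIA and slide 2 WT brains. By the records' names the disease comparison is slide 2 against slide 1, where the median was 0.039 with 0 of 30 genes called (camera adjusted p = 0.909). The rise that these names would bring was thus not seen over all arrays. The activated microglia score in brain ran from -0.86 to 0.77 on slide 2, around the -0.45 to -0.15 of slide 1, so the test does not decide the naming. Without replicate 2 of slide 2 the median was -0.26 with 7 lower and 0 higher (camera adjusted p = 0.000116; 0.717 with an estimated correlation), against the records' names, but that brain was left out for its high microglia score. Between slides 3 and 1 the median was 0.97 with 21 of 30 higher (0.813 with an estimated correlation), which is untreated against treated by the tables' names and treated against WT by the records'. Recovery was 0.912 by the tables' names and 0.144 by the records', which bears on the naming only if the treatment worked and no effect of slide 3 alone gave the higher value. The naming stays open, and the microglia tests take as given that microglia are activated in untreated disease. A treatment that itself activates microglia was not tested, and no array was moved between groups.

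Replicate 2 of slide 2 differed from its slide in both tissues, although its brain and blood are not stated to be from one mouse. Their distances from the group means correlated with r = 0.049, the highest of that brain with any blood array of the slide. Naglu lay below the lowest of the other 11 arrays by a gap of -3.12 in brain and -5.3 in blood, and of 22399 probes it was the only one lower by more than 2 in both tissues for any of the 12 replicates. The gap on separate arrays, with 0 spots marked as outliers, argues against a faulty spot, and a swap with a mouse of slide 3 is argued against because all brains of that slide lay at least 1.29 above the other 3 of slide 2 in the microglia score. A mouse without Naglu transcript stays an open candidate explanation. Against it, the spot was well above background on the brain array, and in blood it was not, so the transcript was low in brain but not absent by this measure. The design names no such mouse, only 1 probe bears on it and no other measurement tested it.

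Brain and blood changes of slide 2 against slide 1 were weakly related across genes, with r of 0.224 and the same sign in 56.1%. Each slide holds both tissues of 1 mouse group, and the test of the slide set measured genes against probes at background. The correlation over measured genes exceeded that over dark probes by 0.18 (bootstrap interval 0.141 to 0.22). Dark probes carry no labelled RNA, so a slide effect on labelling need not show in them, and the excess excludes no such effect. The correlation fell to 0.047 without the blood array rich in liver transcripts, and to 0.142 with that array kept and the genes high on it left out, so liver RNA may carry part of the relation, and what else that array adds is open. An effect of the slide and one of the mouse group cannot be told apart, since group and slide are the same split.

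Chance as the source of the gene counts was tested by regrouping the 8 arrays of each comparison in all 35 ways. In brain the real split was the only 1 with as many genes in each comparison, with 2810, 6224 and 9496 against at most 8, 2 and 3 in the others. In blood the real split was also the only 1 with as many genes for slide 3 against slide 2 (6 genes, at most 2 in the others) and for slide 3 against slide 1 (477, at most 0). Each of these comparisons, in brain and in blood, meets the rule set beforehand for excluding chance as the source of the count. The real split is also the split by slide, so an effect of the slide would single it out as well. A share of 1 in 35 is the smallest this test can give, and 6 comparisons were tested, so 6 genes against 2 are weak evidence. Both blood counts are fragile, since the first fell to 0 without any of 8 single arrays or with a replicate block, and the other to 3 with the 2 groups alone and to as few as 4 without 1 array. For slide 2 against slide 1 in blood chance cannot be excluded, and the count decides nothing there: the real split called 0 genes by limma (1747 at an unadjusted p under 0.05), so all 35 splits give as many by construction. Another split called 2293: it sets replicates 1 and 3 of slide 2 with replicates 3 and 4 of slide 1 against the other 4. Those 4 were the dimmest of the 8 (75th percentile of signal 24.3 to 44.4, against 52.4 to 114.5), so the split follows the amount of signal and need not be biological.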

How the results depend on the processing

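The direction of the named genes held in most settings. Over the alternatives other than leaving out a mouse, 1876 values of named genes were computed: 1519 kept their direction and their side of the threshold, 233 kept the direction but were no longer called, 1 became called and 123 changed sign. Over the settings that left out 1 mouse, 1182 of 1428 kept both, 241 were no longer called and 5 changed sign. The tissues differed in this. Without blood replicate 2, 3 or 4 of slide 3, or 3 or 4 of slide 1, 25 of 28 blood values were no longer called. Without blood replicate 1 or 2 of slide 1, or 2 of slide 2, at most 2 of 28 were lost. In brain at most 6 of 91 values were no longer called without any 1 mouse. The settings that matched the tables' columns to arrays, took the tables' names for the arrays, centred on detected probes, or left out arrays that stand apart, brains with low hypothalamic transcripts or liver-rich genes were chosen after seeing the data. Where no reason is given below, the cause was not tested.

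Taking the tables' names exchanges the comparisons by construction. With the arrays so named, brain counts were 6224 for untreated against WT, 9496 for treated against untreated and 2810 for treated against WT, and blood counts 6, 477 and 0. Lists called were 8 and 5 in brain for untreated and for treated against WT, and 3, 7 and 14 in blood. Recovery was 0.912, the correlations between tissues were 0.557 and 0.478, and the tissue differences 2 and 176. With the deposited table by its own names, brain counts were 6018, 9408 and 2368, blood counts 1, 348 and 0, and lists in blood 4, 12 and 15. Recovery was then 0.938 and the correlations were 0.584 and 0.475. With the table's columns matched to arrays, blood slide 3 against slide 2 had 1 gene, the correlation for slide 3 against slide 2 was 0.584, and 12 lists were called in blood for slide 3 against slide 1.

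Array weights and leaving out arrays moved the blood counts most, and other scalings mostly lowered them. In blood between slides 3 and 2, median centring, normexp with the 75th percentile, no filter on dim probes and a replicate block gave 0 genes, normexp with quantile and the mean over probes 1, quantile and no intensity trend 2, the 2 groups alone 420 and array weights 3102. In blood between slides 3 and 1, the 2 groups alone gave 3, median centring 42, no filter 66, a replicate block 139, quantile 195, normexp with quantile 244, centring on detected probes 299, no trend and the mean over probes 314 each, and array weights 3004. Leaving out the pair of arrays that stand apart gave 1, 2513 and 4139 genes in the blood comparisons, and 7 lists for slide 2 against slide 1. Array weights reduce the influence of arrays far from their group, and the pair left out holds the blood array rich in liver transcripts.

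In brain, slide 2 against slide 1 gave 1499 genes with normexp and the 75th percentile, 1621 with median centring, 1576 without the pair that stands apart and 1434 without the slide 1 brains with low hypothalamic transcripts. A 2-fold threshold left 385, 728 and 1481 genes in the brain comparisons, and a recovery of 0.079. Recovery was 0.193 without the pair and 0.067 without the brains with low hypothalamic transcripts.

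No list was called with an estimated correlation in any of the 6 comparisons, where the count was 0. fry called 0 in each blood comparison and 2 in brain for slide 2 against slide 1. For that brain comparison 9 lists were called without the brains with low hypothalamic transcripts and 10 without the pair. Array weights gave 13 lists for slide 3 against slide 1 in brain, 3 in blood, and 8 in blood for slide 2 against slide 1. No filter on dim probes gave 13 for slide 3 against slide 2 in brain, 10 for it in blood and 14 in blood for slide 3 against slide 1. normexp with the 75th percentile gave 9 and 13 in these blood comparisons. In blood for slide 3 against slide 1, centring on the median or on detected probes gave 12 and the mean over probes 11.

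The correlation between tissues for slide 2 against slide 1 was 0.18 without a filter, 0.272 and 0.275 with normexp followed by quantile or the 75th percentile, 0.142 without liver-rich genes and 0.029 without the pair. The correlation for slide 3 against slide 2 was 0.36 without a filter, 0.567 without liver-rich genes, 0.529 without the pair, 0.545 with quantile, 0.548 with the mean over probes, 0.57 and 0.578 with normexp, and 0.581 with a strict filter. Tissue differences for slide 2 against slide 1 numbered 1 with quantile, 6 with normexp and quantile, and 37 without the pair. Those for slide 3 against slide 2 numbered 1 with median centring, quantile or a strict filter, 11 and 42 with normexp, 239 without the pair and 516 with array weights.

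Leaving out 1 mouse gave 1224 to 2888, 4698 to 6779 and 7581 to 9485 genes in the brain comparisons, and 0 to 0, 0 to 383 and 4 to 2733 in blood. Lists called ranged from 4 to 10, 5 to 10 and 7 to 12 in brain and from 10 to 20, 3 to 5 and 4 to 15 in blood. Recovery in brain ranged from 0.106 to 0.226, the correlations from 0.047 to 0.275 and from 0.533 to 0.561, and the tissue differences from 0 to 304 and from 2 to 59. Fewer arrays leave less power, yet some of these counts rose.

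Sgsh was called only with the mean over probes, in brain for slide 3 against slide 1 (0.35, adjusted p = 0.0172), and its small changes crossed 0 in some of the other comparisons. In brain between slides 3 and 2 it was 0.065 and 0.045 with normexp, 0.002 with quantile, 0.062 with median centring, 0.007 with array weights, 0.095 with the mean over probes and 0.046 with the table matched to arrays. Without 1 mouse it ranged from -0.11 to 0.101. For slide 2 against slide 1 in blood it was 0.18 with median centring, 0.045 with array weights, 0.10 with the mean over probes and 0.22 without the pair, and ranged from -0.54 to 0.23 without 1 mouse. In blood between slides 3 and 1 it was 0.024 with normexp and the 75th percentile, 0.36 with median centring, 0.26 with array weights, 0.19 with the mean over probes and 0.37 without the pair, and ranged from -0.41 to 0.37 without 1 mouse.

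The remaining sign changes arose with the deposited table read by its own names, where each comparison sets other arrays against each other. In brain, untreated MPS IIIA against WT by the tables' names gave Obox3 -0.84, Psmc3ip -0.77, Trat1 -0.29, Ttn -0.55, Mid1 -0.085, Alb 1.00, Ahsg 1.13 and Mup18 0.89. Mup9 was at 0.73, Mup19 0.72, Mup17 0.66, Serpina3k 0.93, Mup20 0.85, Gabra6 0.35, Dnajb9 0.46 and Xbp1 0.24. Bag3 was at 0.81, Hspa4l 0.015 and Ier2 0.10. In brain, AAV-treated against untreated MPS IIIA by the tables' names gave Glycam1 -1.17, Scgb1b7 -1.70, Treml2 -0.84, Tnfsf8 -0.60, Krt6a -1.04, Serpinf2 -0.093, Prl2c5 -0.80 and Obox6 1.51. Olfr715b was at 1.08, Pom121l2 1.09, Spatc1 1.15, Vmn1r240 2.29, Olfr1466 1.99, Zfp345 0.51, Ms4a19 1.59 and Cd74 -1.15. H2-DMb1 was at -1.04, Stat3 -0.48, Vim -0.52, C4b -1.49, Cfp -0.31, Oas2 -0.23, Gbp3 -0.45 and Sumf1 -0.54. Gusb was at -0.60, Cd63 -0.88, Trem2 -1.73, S100a9 -1.39, Elane 0.18, Uqcrb -0.49 and Sdha 0.42. In brain, AAV-treated MPS IIIA against WT by the tables' names gave Sgsh -0.25, Prm1 -2.05, Tnp2 -1.11, Scgb1b7 -0.29, Myl10 -1.001, Cga -1.65, Hsfy2 -0.52 and Sult1c2 -0.76. Slc6a3 was at -2.96, Alb 6.20, Mup9 6.70, Ahsg 6.01, Fabp1 5.25, Mup20 5.97, Fabp2 1.94 and Cyp2c50 2.40. Serpina4-ps1 was at 3.11, Cd74 -0.13, H2-DMb1 -0.24, Ddit3 0.23, Manf 1.098, Hsp90aa1 0.44, Hspe1 0.27 and Trim30a -0.10. Ifi27 was at -0.12, Man2b1 -0.28, Lgals3bp -0.30, Cd63 -0.042, Aif1 -0.56, Mpo -0.39 and S100a9 -0.11. In blood, untreated MPS IIIA against WT by the tables' names gave Sgsh 0.19, and AAV-treated against untreated MPS IIIA gave Tcp11 -1.35. In blood, AAV-treated MPS IIIA against WT by the tables' names gave Sgsh 0.47, Mpo -0.53, H2-Eb1 -1.11, Ltf -1.22, Nxpe4 -1.05, Marco -0.44, H2-Oa -1.53 and Cbr2 -1.20. Car14 was at 1.83, Olfr704 0.44, Obox1 1.102, Olfr332 0.40, Rbmy 0.18, Theg 0.75, Glp2r 0.28 and Ccdc151 0.25. Psmb10 was at -0.35, Itgax -0.87, Trem2 -1.54, Ear2 -1.79, Cd300e -1.002, Treml1 -0.49, Rps15 -0.57 and Rps18 -0.18.

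The authors' tables were not used for tissue differences, since each tissue was normalized apart, and a fit with slide as a block was not run because slide and group are the same split. Recovery in blood had no value by the records' names. Replicate numbers showed no clear pairing of the samples, with r from -0.088 to 0.3 in brain, -0.31 to 0.333 in blood and -0.115 to 0.175 between tissues. The array of the same number was the best match for 3 of 12 in brain, 2 of 12 in blood and 6 of 12 between tissues. Whether brain and blood of a number come from the same mouse thus stays open. Signal over background limits blood, where at most 47.2% of probes were above background.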

Other observations

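Enzymes that break down heparan sulfate, the substrate stored in MPS IIIA, went both ways in brain. Of 11 measured genes 4 were higher and 1 lower on slide 3 than on slide 2, 5 and 1 when adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.261; fry adjusted p = 0.0414). Genes that build heparan sulfate showed no direction, with 4 of 34 higher and 5 lower and a median of -0.04. Synaptic genes had a median change of -0.01 with 3 of 32 higher and 5 lower, and myelin genes one of -0.14 with 0 of 19 higher and 1 lower. Genes of cell division were called by fry (adjusted p = 0.0414) but not by camera (adjusted p = 0.147), with a median of 0.20.

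Scores of transcripts typical of brain regions and of other organs differed between brains, and the cause was not tested. The hypothalamus and pituitary score was -1.83 and -1.76 in replicates 1 and 2 of slide 1 and at least -0.40 in the other 10 brains. The choroid plexus score was -1.08 and -1.29 in replicates 3 and 4 of slide 1 and at least -0.22 in the others. Germ cell transcripts, a list chosen after the values were seen, reached a score of 6.38 in replicate 2 of slide 3 and at most 0.74 in the other brains. Liver list scores were 1.33 to 4.08 on slide 1 and 1.74 in that same brain of slide 3, and 9.83 in blood replicate 1 of slide 1. Of 34808 names, 1571 were over 8-fold higher in that blood array than in the median of the other blood arrays. In brain 1360 of them were tested, 5.3% of all names. On slide 2 against slide 1 they made up 15.2% of the names called lower (190 of 1251) and 3.4% of those called higher (53 of 1559). On slide 3 against slide 1 these shares were 6.6% (337 of 5069) and 4.8% (211 of 4427).

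A donor-strain segment around the mutated gene would put called genes near Sgsh on its chromosome. The test was planned for slide 2 against slide 1, and the test by the tables' names was chosen after the result was seen. Of genes within 20 Mb of Sgsh 9.2% were called between slides 2 and 1 in brain, against 10.7% elsewhere (odds ratio 0.848, interval 0.588 to 1.19, Fisher's exact p = 0.374). Between slides 3 and 2 the shares were 23.7% and 22.6% (odds ratio 1.07, interval 0.839 to 1.35, Fisher's exact p = 0.592). Neither test showed an excess near the gene.

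The authors' tables list, of 59305 spots, 6598 in brain with an adjusted p under 0.05 between the groups they name untreated MPS IIIA and WT, 12630 between untreated and AAV-treated, and 1845 between AAV-treated and WT. In blood these were 4, 197 and 0.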
